A study of Mus musculus with 6 samples.

How the data were processed

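Signals of 12488 probe sets were measured on 6 Affymetrix MGU74Av2 arrays, which carry short oligonucleotide probes for mouse transcripts. Per the labels, total RNA of the tibialis anterior of 4 animals was pooled for each group and each pool was split onto 2 arrays, lettered A and B. The authors deposited 1 linear intensity per probe set and array. All deposited intensities lay above 0, and the 6 arrays had nearly equal trimmed means of 500.3 to 500.4 after removal of 2% of values at each end, which is what scaling every array to one target gives. The software, background correction and summary of probes behind these intensities are not given in the sources used here. A global scaling of this kind measures each gene relative to the rest of its array, so a change shared by most genes would not show.

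The probe table, from the platform annotation, gave 1 gene for 10833 probe sets, several genes for 396 and none for 1193, and 66 further probe sets were Affymetrix controls. Gene IDs of 10817 of the 10833 probe sets were found in a RefSeq gene table of the GRCm38.p6 assembly, which changed 0 symbols, and that table served for names only. Probe sets with several genes or none were kept out of the gene counts. For the 2073 of 8251 genes with more than 1 probe set, the probe set with the highest mean signal over the 6 arrays was used. Of called genes with another measured probe set, 19 of 66 (eccentric against control), 1 of 12 (isometric against control) and 6 of 19 (eccentric against isometric) had one of opposite sign. The text says so where this holds for a named gene. Probe sets of some named genes are open to cross-hybridisation, those of Actc1, Atf3, Cd68, Cryab, Fcgr1, Junb and Tradd among them.

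Each array was multiplied so that its trimmed mean equalled the average of the 6, by factors of at most 1.000022. Values below a floor at the 40th percentile of all values (a signal of 120.8) were set to it, and log2 was taken. A gene entered a comparison when it lay above the floor on both arrays of at least 1 of the 2 pools. It was called higher or lower when the mean log2 signals of the pools differed by at least 1, a 2-fold difference, and all 4 pairings of an array of one pool with an array of the other had the same sign. Chance alone gives the same sign in all 4 pairings for 33.3% of genes, so the size of the difference does most of the selecting. Because both arrays of a group carry the same pooled RNA, a group is 1 biological sample, and no p-value for the type of contraction was computed. The number of calls that differences between arrays of one pool would give was taken from 100 simulated comparisons, with noise drawn for each gene separately. Folds are ratios of geometric means of floored signals, and where a pool lay at the floor on both arrays the fold is a lower bound, written as at least N-fold. The precision of every value is limited by the number of arrays, 2 per pool.

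The 32 gene lists, holding 642 genes of which 536 were on the array, the comparisons, the size rule and the rule for naming genes were fixed before the data were examined. For each list the median log2 difference of its measured genes was set against 10000 random lists of the same size matched on signal in 20 bins, and the percentile describes these pools only. The list of Z-disc and mechanical-stress genes was drawn up knowing that published work on this model names Csrp3, Ankrd1, Ankrd2 and Xirp1. The text names, for each comparison, the 10 highest and 10 lowest called genes above the floor on all 4 arrays, the 3 called genes per direction with the largest lower bounds, up to 4 called members of each list, and 8 preset genes. Of the preset genes 6 were on the array (Csrp3, Ankrd1, Ankrd2, Xirp1, Myog and Des), and Fbxo32 and Trim63 were not analysed here. Not every gene that the rule allows is printed. Genes and list members named outside this rule were chosen after their values were seen, and the text says so.

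The size rule was tested on simulated data with 200 changed genes in 20 runs per comparison. For the eccentric against the control pool it called 89.5% of 3-fold, 95.9% of 4-fold and 99.6% of 8-fold changes in the right direction, with 19.2 unchanged genes called on average among 5682. For the isometric against the control pool these shares were 90.9%, 94.8% and 99.6%, with 33.1 unchanged genes called among 5574. For the eccentric against the isometric pool they were 91.7%, 95.5% and 99.9%, with 16.3 among 5622. As an alternative, limma was run on the 6 arrays with Benjamini-Hochberg adjustment at 0.05, without and with the array letter as a block. That test measures the spread between arrays and compares these pools, not the conditions. Other alternatives changed the scaling, the floor, the filter, the fold threshold and the choice of probe sets, and each of the 6 arrays was left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, were used.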

Results

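Gene expression was measured in the tibialis anterior, a muscle of the shin, of mice 48 h after 50 eccentric contractions, in which the active muscle is lengthened, or 50 isometric contractions, in which its length is held. The control pool came from the opposite legs, which had been stimulated only for a measurement of torque. The labels do not say whether the legs of the control pool belonged to animals given eccentric or isometric contractions. Each group was 1 RNA pool of 4 animals on 2 arrays, so values are given as mean signal ± SD over n = 2 arrays of 1 pool, and this SD covers labelling and hybridisation, not animals. Median signals were 187 to 197, and 59.2% to 61.2% of probe sets on each array lay above the floor. The log2 difference between the 2 arrays of a pool had an SD across genes of 0.391 in the control pool, 0.274 in the eccentric pool and 0.394 in the isometric pool. The ratio of 3' to 5' signal of beta-actin, a sign of RNA quality, was higher in the eccentric pool, at a log2 of 0.44 against 0.04 in the control pool and 0.21 in the isometric pool. That of Gapdh was 0.12 in the eccentric and 0.10 in the isometric pool against -0.06 in the control pool, with isometric B at 0.27 and isometric A at -0.07.

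The comparison of the eccentric with the control pool asks which transcripts differed 48 h after lengthening contractions. Genes of the Z-disc and of the response to mechanical stress were among those with the largest differences. Ankrd1, an ankyrin-repeat protein that binds titin, had a signal of 2949 ± 56.0 in the eccentric pool against 373 ± 141 in the control pool, an 8.21-fold difference. Csrp3, the muscle LIM protein, was 5.74-fold higher at 6263 ± 341 against 1091 ± 59.1. Xirp1, an actin-binding protein of cell junctions, was 4.73-fold higher at 10653 ± 368 against 2254 ± 3.9. Ankrd2, a relative of Ankrd1, was 4.05-fold higher at 4253 ± 10.5 against 1053 ± 77.2. Of 14 measured members of the Z-disc list, 6 were higher, 0 were lower and 8 did not pass the 2-fold rule. The median log2 difference of that list was 0.49, at percentile 100 of 10000 random lists. Because the list was drawn up knowing that published work names these 4 genes, its count is not independent evidence. Des, encoding the intermediate filament desmin, did not pass, at 4249 ± 77.8 against 3758 ± 108.

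**Figure D1:**
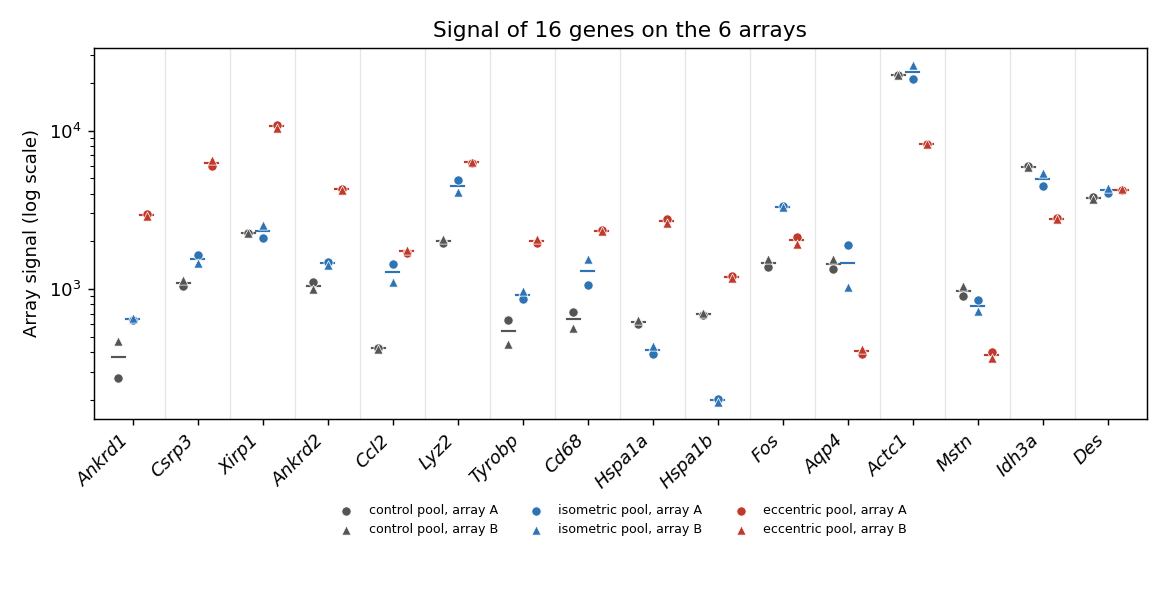
Array signal (log scale) of 16 genes on the 6 arrays, with circles for array A, triangles for array B and short bars for the mean of each pool (control grey, isometric blue, eccentric red). Ankrd1, Csrp3, Xirp1 and Ankrd2 lie 4.05-fold to 8.21-fold higher in the eccentric than in the control pool, while Aqp4 and Actc1 lie lower there, and Hspa1b has its lowest signals in the isometric pool. Lyz2, Fos and Idh3a are described with their lists, and Mstn among single genes.

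Markers of macrophages and monocytes were higher in the eccentric pool across nearly the whole list. Of 26 measured members 20 were higher, 0 were lower and 6 did not pass, all 26 had differences above 0, and the median log2 difference was 1.41 (percentile 100). Of the 26 genes, 20 lay above the floor on both control arrays. Cd68, a lysosomal glycoprotein of macrophages, had 2336 ± 32.0 against 645 ± 106. Tyrobp, a signalling adaptor of myeloid cells, had 2014 ± 70.1 against 545 ± 137, and the scavenger receptor Msr1 was 3.97-fold higher. The other probe set of Msr1, with a log2 difference of 0.9, was not called. Cd53, a leukocyte tetraspanin, had 930 ± 79.1 against 79.8 ± 87.4, with 1 control array below the floor. The chemokine receptor Ccr2, which is found on monocytes, was 4.91-fold higher. In the list of chemokines and cytokines 9 of 15 members were higher and 0 lower, with a median of 1.23. Ccl9 was 4.21-fold higher, and Ccl2 and Ccl7, which attract monocytes, were 4.07-fold and 4.06-fold higher. Of 7 MHC class II genes 5 were higher, H2-Aa at 3475 ± 79.5 against 1028 ± 62.5 among them, and the median was 1.35. The interferon-response list had a median of 0.77 over 11 members, of which Psmb8 was higher, where array noise alone reached 1 call, and 10 did not pass. Adam8 and Lst1, both expressed in myeloid cells, lay below the floor in the control pool and were at least 6.05-fold and at least 4.45-fold higher.

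Some heat shock genes, annexins and metallothioneins were also higher in the eccentric pool. Hspa1a, an inducible chaperone of the Hsp70 family, had 2685 ± 121 against 618 ± 23.8, a 4.35-fold difference. Hsp90aa1 was 3.49-fold higher, and Cryab, a small chaperone that is also a member of the Z-disc list, was 2.98-fold higher at 9641 ± 140 against 3242 ± 144. Of 25 heat shock genes and chaperones 7 were higher and 18 did not pass, with a median of 0.39 (percentile 100). Of 11 annexins and membrane-repair genes 7 were higher and 4 did not pass, with a median of 1.12. Anxa2, which takes part in membrane repair, had 6190 ± 36.9 against 1690 ± 10.3, and S100a4 was 4.33-fold higher. Mt2, a metal-binding protein, had 15077 ± 1104 against 4965 ± 46.7, and Hmox1, which breaks down heme, was 2.27-fold higher. The list of metallothionein and oxidative stress genes had 3 of 17 members higher, but its median of 0.09 (0.00 to 0.18 with 1 array left out) lay within the range of random lists (percentile 93.6). Atf3, a stress-induced transcription factor, was 4.87-fold higher, and 2 of 20 immediate early genes were higher with a median of 0.25 (percentile 98.6). In the cell cycle list 4 of 24 members were higher, Stmn1 at 3.83-fold and Mcm5 at 3.42-fold among them, and the median was 0.56. Of 35 extracellular matrix genes 6 were higher, including the protease inhibitor Timp1 at 3.19-fold, and the median was 0.34. Lox, which cross-links collagen, was 2.45-fold higher on the probe set used, but a dimmer probe set of the gene had a log2 difference of -0.41.

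Genes of energy metabolism were lower in the eccentric pool as lists, mostly by less than 2-fold. None of 37 measured mitochondrial respiratory chain and citrate cycle genes had a difference above 0, and the median was -0.57 (percentile 0.0), although only 4 were called lower (Ndufs4, Atp5pb, Cycs and Idh3a) and 33 did not pass. Idh3a, a subunit of a citrate cycle dehydrogenase, had 2783 ± 17.9 against 5933 ± 87.7. Of 19 measured members of the glycolysis list 2 were lower, Gpd1 and Phka1, neither an enzyme of glycolysis itself. The list median was -0.53 (percentile 0.20). Of 17 genes of fatty acid oxidation and lipid handling 0 were called, with 0 members above 0 and a median of -0.55 (percentile 0.02). Fast-fibre contractile genes had a median of -0.28 (-0.47 to -0.17 with 1 array left out) with 0 of 17 called. That median lay within the range of random lists of such bright genes (percentile 40.9). Among single genes, the water channel Aqp4 had 405 ± 19.8 against 1439 ± 142, a log2 difference of -1.83. Cardiac alpha-actin, Actc1, had 8253 ± 50.0 against 22314 ± 0.9, a log2 difference of -1.44 on a probe set open to cross-hybridisation with other actins, and its second probe set was also lower. Myostatin, Mstn, which restrains muscle growth, had a log2 difference of -1.34, and Ghr, the growth hormone receptor, one of -1.48. A second probe set of Ghr had a log2 difference of -0.66 and was not called. Kcnd3, a potassium channel, lay below the floor in the eccentric pool and was at least 3.57-fold lower. Myog, a myogenic transcription factor, was 2.12-fold higher at 950 ± 259 against 439 ± 34.9. The myogenic list had 2 of 19 members higher, 1 lower and a median of 0.10 (percentile 84.9), which was 0.03 to 0.24 with 1 array left out.

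In all, 353 of 5682 genes passed the rule between the eccentric and the control pool, 293 higher and 60 lower, where array differences alone gave 18.9 calls on average and at most 30 in 100 simulations. Of 31 lists with at least 3 measured genes 14 lay outside the central 95% of random lists, 11 above and 3 below. If genes differed independently, 1.55 would. Members of a list can move together between arrays, so 1.55 is not the number expected without an effect of the contractions. The fast-fibre median of the isometric against the control pool, for 1, ran from -0.44 to 0.23 by array pair. With control A and isometric B left out, 2 arrays whose 18S rRNA was brighter than that of their partners, 369 genes passed, with 20 macrophage markers, 9 chemokines and 5 Z-disc genes called higher, and 4 mitochondrial genes and the Z-disc gene Tcap (named after its values were seen) called lower. Spiked-in controls were brighter on control A (geometric mean signal 2422 against 1892 on control B) but only slightly on isometric B (2436 against 2340 on isometric A). Leaving out 1 array ended the calls of Gadd45a, Atp2a2 and Junb (without control A), Bgn, Phka1, Cycs and Mt1 (control B), Myog, Gadd45a, Bgn and Atp5pb (eccentric A), and Ache, Fcgbp and Phka1 (eccentric B). That left 1 member of the glycolysis list lower without control B or eccentric B, and 1 immediate early gene higher without control A. It left 1 and 0 myogenic genes higher without control A and without eccentric A. limma on the arrays, which compares these pools only, called 540 genes, 383 higher and 157 lower, with 278 of the 353 among them, and 294 with the array letter as a block. Among named genes that passed the size rule it did not call, without a block, Ache, Atp5pb, Cycs, Dnajb5, Fcgbp, Junb, Kcnd3, Mcm5 and Myog.

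The comparison of the isometric with the control pool asks the same of contractions without lengthening. A minority of the genes for immediate early transcription factors and of the macrophage markers passed the rule as higher in the isometric pool. Fos had 3316 ± 19.8 in the isometric pool against 1460 ± 127 in the control pool, a 2.27-fold difference, while its 2027 ± 142 in the eccentric pool did not pass the rule against the control pool. Junb was 3.16-fold higher and Atf3 2.54-fold higher, each on a probe set open to cross-hybridisation. The other probe set of Junb was also called higher, but that of Atf3, with a log2 difference of 0.61, was not called. Of 18 immediate early genes 3 were higher and 15 did not pass, with a median log2 difference of 0.52 (percentile 100). Ccl2 had 1275 ± 231 against 424 ± 3.8, and 2 of 12 chemokines and cytokines were higher, no more than the 2 that array noise alone reached, with a median of 0.37. Of 23 measured macrophage markers 5 were higher, 0 were lower and 18 did not pass, 21 lay above 0, and the median was 0.48 (percentile 100). Lyz2, the macrophage lysozyme, had 4496 ± 587 against 2017 ± 75.1, and Msr1 was 2.24-fold higher.

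Other lists above the range of random lists were annexins and membrane-repair genes (median 0.44, S100a4 higher, where array noise alone reached 1 call), MHC class II genes (median 0.42, 0 of 7 called), extracellular matrix genes (median 0.22, 0 of 34 called) and cell cycle genes (median 0.18, Stmn1 and Mcm5 higher). Lists below it were lymphocyte markers (median -0.47 over 5 genes, Cd4 lower) and red blood cell genes (median -0.32 over 3 genes, 0 called). With 1 array left out these medians were -0.77 to -0.17 for lymphocyte markers, -0.52 to -0.22 for red blood cell genes and 0.03 to 0.34 for cell cycle genes, and without both control A and isometric B the lymphocyte median was -0.12 with 0 called and the red blood cell median -0.19. Rrad, a small GTPase of muscle, was 2.63-fold higher at 1141 ± 52.1 against 435 ± 12.1, Il1rn, the interleukin-1 receptor antagonist, was 2.51-fold higher, and Tradd was 3.56-fold higher on a probe set open to cross-hybridisation. Hspa1b, an inducible chaperone nearly identical in sequence to Hspa1a, had 198 ± 5.3 against 699 ± 16.9, a log2 difference of -1.82, and its probe set could share signal with that of Hspa1a. Pspn and Traip were also lower, with log2 differences of -1.63 and -1.45. Of the Z-disc list 0 of 14 members were called and its median was 0.04 (percentile 81.8). With 1 array left out the median was 0.08 to 0.18 and at most 1 member was called higher. Ankrd1 had 645 ± 13.6 against 373 ± 141, Csrp3 1553 ± 118 against 1091 ± 59.1, Ankrd2 1452 ± 41.9 against 1053 ± 77.2 and Xirp1 2318 ± 326 against 2254 ± 3.9, none of which passed the rule. Mitochondrial genes had a median of -0.08 with 0 of 37 called (percentile 11.2), and heat shock genes one of 0.08 with 1 of 25 called. With 1 array left out these medians were -0.21 to -0.01 and 0.02 to 0.13.

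In all, 69 of 5574 genes passed, 51 higher and 18 lower, where array differences alone gave 31.8 calls on average and at most 45, with at most 26 higher and at most 28 lower, so the number of lower calls was no larger than array noise gave. limma called 1 gene, Hspa1b (578 had an unadjusted p below 0.05), and 0 with the array letter as a block (521 unadjusted). The count was 206 without control B, 145 without isometric A, 123 without isometric B and 136 with control A and isometric B both left out, when 2 macrophage markers were called. Without isometric B 3 macrophage markers and 1 chemokine were called, without control B 1 chemokine, and without control A 1 cell cycle gene. Calls lost when 1 array was left out included those of Cd4, Cd52, Lgals3, Mcm5 and Notch2 (control A), Cxcl1 and S100a4 (control B), Lgals3 and Notch2 (isometric A), and Msr1, Mcm5, Cxcl1 and Csf3r (isometric B).

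The comparison of the eccentric with the isometric pool asks what lengthening adds to activity. Heat shock and Z-disc genes were among those with the largest differences. Hspa1a had 2685 ± 121 in the eccentric pool against 414 ± 34.6 in the isometric pool, a 6.50-fold difference, and Hspa1b was 6.04-fold higher at 1195 ± 23.3 against 198 ± 5.3. Xirp1 was 4.62-fold, Ankrd1 4.57-fold, Csrp3 4.04-fold and Ankrd2 2.93-fold higher. Of 14 Z-disc genes 6 were higher, 0 were lower and 8 did not pass, with a median of 0.39 (percentile 99.99). Of 25 heat shock genes 4 were higher, with a median of 0.29. Hspa1a and Hspa1b were among these, and their probe sets could share signal. Against the control pool Hspa1b had log2 differences of 0.77 in the eccentric pool, not called, and -1.82 in the isometric pool. Most of its difference between the exercised pools thus lay in its low isometric signal. For Hspa1a these values were 2.12 and -0.58.

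Macrophage markers differed between the exercised pools as well, with 10 of 26 higher, 0 lower, 16 not passing, all 26 above 0 and a median of 0.86 (percentile 100). Fcgr1, an Fc receptor of macrophages, had 707 ± 58.0 against 296 ± 66.4, Mrc1, the mannose receptor, was 2.80-fold higher, and Adam8 was 5.61-fold higher. The other probe set of Fcgr1, with a log2 difference of 0.74, was not called. Among chemokines and cytokines 5 of 15 were higher with a median of 0.72, Ccl9 at 2.94-fold and Ccl8 at least 4.00-fold. Of 7 MHC class II genes 3 were higher (median 0.92), although the second probe set of H2-DMa had a log2 difference of -0.03. Annexins and membrane-repair genes had a median of 0.60 with 2 of 11 higher. The neutrophil genes S100a8 and S100a9 were 2.92-fold (1 isometric array below the floor) and at least 2.36-fold higher, 2 of 8 members of their list, with a median of 0.50 (percentile 99.5) that was -0.17 when only genes above the floor on all arrays were kept and 0.10 to 0.81 with 1 array left out.

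Lower in the eccentric than in the isometric pool were Aqp4 at 405 ± 19.8 against 1466 ± 622, Actc1 at 8253 ± 50.0 against 23616 ± 3521, and Gpd1, a glycerol-3-phosphate dehydrogenase, at 1575 ± 125 against 4095 ± 42.8. Itm2a, a membrane protein of differentiating muscle, had a log2 difference of -1.41, and Nrep one of -1.60. The fatty acid oxidation list had a median of -0.56 with 0 of 17 members above 0 and 1 called lower, Ucp3, a mitochondrial carrier protein. The mitochondrial list had a median of -0.49 with 1 of 37 called (Cycs, and 0 to 2 genes with 1 array left out), and the glycolysis list one of -0.43 (-0.55 to -0.23 with 1 array left out) with 1 of 19 called. Fancc was called lower on the probe set used, but its second probe set had a log2 difference of 0.32.

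In all, 135 of 5622 genes passed, 97 higher and 38 lower, where array differences alone gave 16.7 calls on average and at most 33. Of 31 lists 17 lay outside the central 95% of random lists. The count was 219 without isometric A and 204 without isometric B, and limma called 75 genes without a block, 64 of the 135 among them, and 8 with the array letter as a block. Calls that limma without a block did not give included those of Aqp4, Mrc1, Cycs, Fancc, Timp1, S100a4, H2-DMa and H2-DMb1. Calls lost when 1 array was left out included H2-DMb1, H2-DMa, C3ar1 and Cycs (eccentric A), Ache, Prcc, Timp1 and S100a4 (eccentric B), Fancc, H2-DMb1, H2-DMa, Lox, Timp1, Cycs and Anxa2 (isometric A), and Ucp3, Tbx2 and S100a4 (isometric B), so that 1 MHC class II gene was called without eccentric A or isometric A, and 4 annexins and membrane-repair genes without eccentric A but 1 without eccentric B or isometric B.

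**Figure D2:**
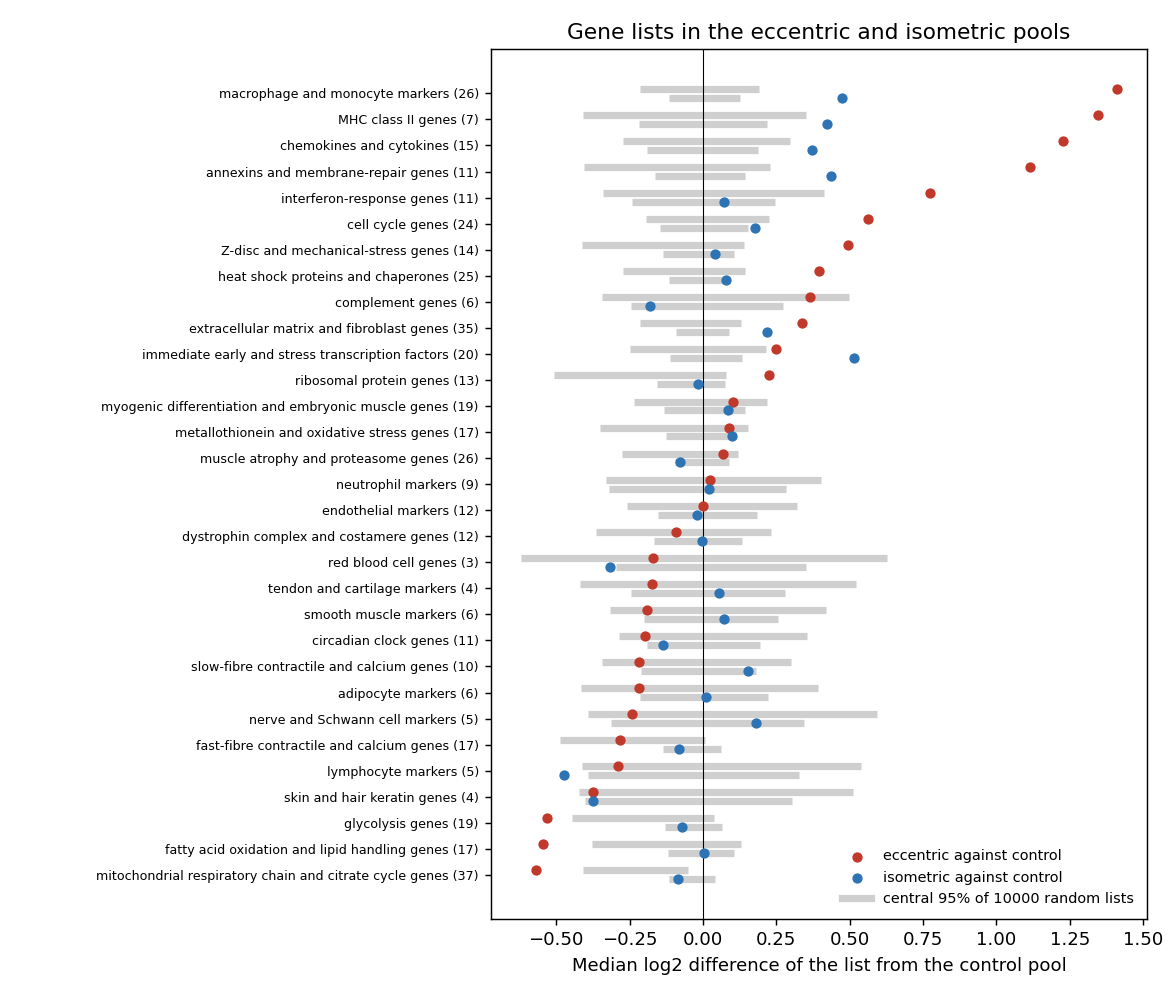
Median log2 difference from the control pool of 31 gene lists in the eccentric pool (red) and in the isometric pool (blue), with grey bars for the central 95% of 10000 random lists matched on signal and, in brackets, the number of genes measured in the eccentric comparison. Macrophage markers lie at 1.41 and 0.48 and mitochondrial genes at -0.57 and -0.08.

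The differences of both exercised pools from the control pool were then compared across genes. Of genes measured in both comparisons (5473), 260 were higher in the eccentric pool and 48 in the isometric pool, and 33 of these were shared, among them Atf3, Ccl2, Cd68, Hal, Junb, Lyz2, Msr1, Rrad and Stmn1, where independent lists would share 2.28. The shared control arrays raise such a number, and with a different control array for each comparison, which was added after the data were seen, 28 and 34 genes were shared where independent lists would share 3.04 and 6.16. For genes chosen as higher in the eccentric arrays with 1 control array and measured against the other, the isometric arrays had medians of 0.34 to 0.43 and the eccentric arrays 1.10 to 1.29. For genes chosen as lower in the same way, which was added after the data were seen, the isometric arrays had medians of -0.24 to 0.00 and the eccentric arrays -1.06 to -0.60. The only shared lower gene was Th (expected 0.20, array noise 5.49 on average), and the only gene called higher in the eccentric and lower in the isometric pool was Saa3, an acute-phase protein, both named after their values were seen. Across 4838 genes above the floor on all 6 arrays, which are not independent replicates, the 2 differences had a Pearson r of 0.618, where array noise alone gave 0.57. Their covariance was 0.0909 against 0.0391 from array noise, a difference of 0.0518. With a different control array for each difference r was 0.31 and 0.283, and part of that may come from the control pool, which both arrays share.

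**Figure D3:**
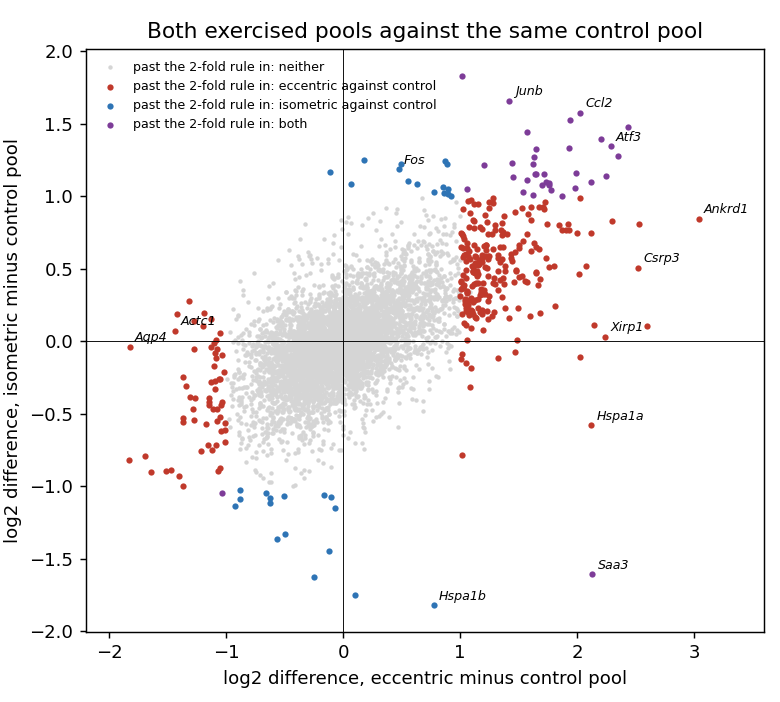
Log2 difference of the eccentric pool (horizontal) and of the isometric pool (vertical) from the same control pool, 1 point per gene measured in both comparisons (5473), coloured by the comparisons in which the gene passed the 2-fold rule. Shared higher calls lie at the upper right (33 genes) and the shared lower call, Th, at the lower left, Ankrd1, Csrp3 and Xirp1 lie far to the right with smaller vertical values, and Saa3, called in both in opposite directions, and Hspa1a lie to the right and below 0.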

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

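For 198 of 5473 genes both eccentric arrays lay on one side of both control arrays and both isometric arrays on the other, where random orders of the arrays would give 122. Random orders assume no difference between any of the pools. A difference of the eccentric pool alone would also raise the count, so 198 against 122 does not show opposite effects. The 6 of the 198 genes that passed the size rule against the control pool in at least 1 exercised pool follow, and the difference between their differences was not tested. Hspa1a had log2 differences from the control pool of 2.12 in the eccentric pool and -0.58 in the isometric pool. Hspa1b had 0.77 and -1.82. Saa3, chosen after its values were seen, had 2.13 and -1.61, with 1 isometric array below the floor. Cln8 had 1.02 and -0.78. Gpd1 had -1.19 and 0.19, and Nrep had -1.32 and 0.28.

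Signals also differed among probe sets that have no single gene name and so stood outside the gene comparisons. Of these 27 were higher and 7 lower in the eccentric than in the control pool, among 742 that entered. In the isometric pool 7 were higher and 6 lower, among 727.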

How the results depend on the processing

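Leaving out control A and isometric B together and the crossed pairing were chosen after seeing the data; the other alternatives were planned. Under 2 other scalings, to a common median and by quantiles, the counts stayed within 1.5 times of those reported. Using the values as deposited changed no count, as it must, since the arrays already had nearly equal trimmed means. No called gene that the naming rule gives changed sign in any setting. In most settings none could, since a call asks for the same sign in all 4 pairings of arrays. Only other scalings and other choices of probe sets could have turned a sign. The setting that counted each probe set by itself followed the same probe set of a gene. Another scaling ended the calls of Bgn and Gadd45a (eccentric against control), Cxcl1 and Lgals3 (isometric against control), and H2-DMa and S100a4 (eccentric against isometric). Lowering the floor to the 20th percentile gave 617 calls for the eccentric against the control pool, 268 for the isometric against the control pool and 337 for the eccentric against the isometric pool, and raising it to the 60th gave 190, 23 and 71. The lower floor admits dim genes, where signal over background limits what can be read, and the higher one leaves out genes or raises their dimmer signals to the floor. Among named genes that still entered a comparison, the higher floor ended the calls of Ache, Atp5pb, Ccl8, Cdk1, Ghr, Kcnd3, Lox, Lst1, Msr1, Ndufs4 and S100a8 (eccentric against control), Cd52, Cxcl1, Egr2, Hal, Il1rn, Mcm5, Notch2, Stmn1 and Traip (isometric against control), and Ccl8, Cln8, Cxcl5, Fancc, Fcgr2b, Lox, Ltb4r1, Pim3, S100a8 and Tgfb1 (eccentric against isometric). Named genes that no longer entered at that floor had no call there either and are not listed. A 1.5-fold threshold gave 1103, 346 and 711 calls and a 3-fold threshold 75, 6 and 22, as a looser or stricter limit must. The share of higher calls was 83.0%, 73.9% and 71.9%, and it was 70.0%, 54.9% and 62.3% at the lower floor. At the 3-fold threshold it was 94.7%, 33.3% and 81.8%, so that for the isometric against the control pool, with 2 higher and 4 lower, the balance turned. Averaging all probe sets of a gene gave 45 calls for the isometric against the control pool; the cause was not tested. Leaving out 1 array gave 369 to 484, 82 to 206 (the highest without control B) and 176 to 219 calls (the highest without isometric A). A single array is not averaged, but that holds alike without control A (82 for the isometric against the control pool) and without control B (206). The cause of this gap was not tested. Leaving out control A and isometric B together gave 369, 136 and 204. The number of lists outside the random range for the isometric against the control pool was 8 to 15 with 1 array left out, against 9, and 15 without isometric B. The correlation of both differences across genes was 0.509 to 0.708 with 1 array left out, the lowest without isometric B and the highest without control B, and 0.31 and 0.283 with control arrays split, where array noise of the control arrays is no longer shared. For the eccentric against the isometric pool the median of the myogenic list (0.20, with a mean of -0.02) was -0.06 at the lower floor and -0.02 to 0.28 with 1 array left out, the lowest without isometric A, and that of the neutrophil list (0.50) was -0.02 at the lower floor and -0.17 with only genes above the floor on all arrays; the cause was not tested. limma on the arrays called 540, 1 and 75 genes without a block. With the array letter as a replicate block it called 294, 0 and 8 (1418, 521 and 989 at an unadjusted p below 0.05). The letters do not pair the arrays by the labels, and array A minus B differences correlated across genes at 0.041 (control and eccentric), -0.146 (control and isometric) and -0.045 (eccentric and isometric). With control A paired with isometric B, the crossed pairing, limma called 421, 0 and 7 genes (1578, 599 and 1143 unadjusted).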

Other observations

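Markers of most other cell types lay within the range of random lists in the eccentric against the control pool. Neutrophil markers had a median log2 difference of 0.02 over 9 genes, S100a8 and S100a9 being higher, and that median was below 0 under 2 other scalings. Complement genes had a median of 0.37 over 6 genes, with Cfp (properdin) 4.43-fold and the receptor C3ar1 2.83-fold higher. Medians were -0.29 for 5 lymphocyte genes, 0.00 for 12 endothelial genes, -0.19 for 6 smooth muscle genes, -0.22 for 6 adipocyte genes, -0.24 for 5 nerve and Schwann cell genes, -0.17 for 4 tendon and cartilage genes, -0.37 for 4 keratin genes and -0.17 for 3 red blood cell genes, with 0 members called in each. Slow-fibre genes had a median of -0.22 with Atp2a2 higher, dystrophin complex and costamere genes -0.09, circadian clock genes -0.20, and muscle atrophy and proteasome genes 0.07 with the lysosomal protease Ctsl 2.27-fold higher. Ribosomal protein genes had a median of 0.23 over 13 genes (percentile 99.8) with 0 called. Several of these medians depended on single arrays. With 1 array left out they were 0.01 to 0.80 for complement (the highest without control A), -0.18 to 0.10 for nerve and Schwann cell, -0.54 to -0.03 for lymphocyte, -0.43 to 0.06 for slow-fibre, -0.49 to 0.03 for adipocyte, -0.41 to -0.03 for red blood cell, -0.23 to 0.26 for neutrophil, -0.12 to 0.04 for endothelial, -0.25 to -0.09 for dystrophin complex and 0.10 to 0.22 for ribosomal protein genes. The ranges were -0.28 to -0.09 for circadian clock, 0.02 to 0.09 for muscle atrophy and proteasome, and -0.23 to -0.09 for tendon and cartilage genes. Of the sex-linked list 1 gene was measured, too few for a median.

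The tests of macrophage RNA and of dilution by RNA of other cells were chosen after the results they bear on were seen; the other tests were planned. For the macrophage markers higher in the eccentric pool, array noise called at most 1 list member higher in 100 simulations against 20 observed. These simulations drew noise for each gene separately, but the list's median by array pair also stayed between 1.29 and 1.49. The fewest called under 2 other scalings was 20. These values argue against array noise and against scaling. RNA of macrophages in the eccentric muscle stays open, since 100% of the 26 measured members lay above the control pool, a share that repeats the pattern and does not test where the RNA came from. Of the 26 genes 20 also lay above the floor in the control muscle. With 1 pool per group, a difference between the animals that were pooled cannot be told apart from an effect of the contractions.

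For the mitochondrial genes lower in the eccentric pool (median -0.57), array noise gave a median no lower than -0.08 in 100 simulations. These drew noise for each gene separately, so noise that list members share is understated. By array pair the median ran from -0.63 to -0.49, and that of the isometric against the control pool from -0.25 to 0.04. Less the median of all genes, the list's median was -0.55 and at most -0.39 under 2 other scalings. Taking off that median cancels a factor common to an array, so only the quantile scaling tested a shift that varies with signal. Random lists of like signal had medians from -0.41 to -0.05 in their central 95%, so genes of like signal were lower in general. The mitochondrial list lay below that range. Dilution of fibre RNA by RNA of other cells would lower fibre-restricted genes alike. The 32 genes taken as such, from the fast-fibre list, the slow-fibre list and the list of dystrophin complex and costamere genes in the same range of signal, had a median of -0.26. That lay above the median of the mitochondrial list by 0.31 (95% bootstrap interval over genes 0.08 to 0.50). Genes of 1 pair of pools are not independent replicates, and it was not checked that each of the 32 genes is restricted to fibres. This interval therefore does not settle whether dilution accounts for all of the difference or part of it. With 1 array left out the fast-fibre median was -0.47 to -0.17 and the mitochondrial median -0.60 to -0.50. A difference between the pooled animals, RNA quality and an effect of the contractions stay open and untested, and the 3' to 5' ratio of beta-actin was higher by 0.41 (log2) and that of Gapdh by 0.18 in the eccentric than in the control pool.

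For the genes higher in the eccentric pool that were also higher, by less, in the isometric pool, noise of the shared control arrays was set apart by using a different control array for each difference. The covariance across genes was then at least 0.0546, against at most 0.0038 in 100 simulations, which drew noise for each gene separately. If 1 isometric array were mislabelled, one of the pair would lie near 0 over the genes higher in the eccentric pool, but the lowest median log2 difference of an isometric array over genes chosen with the other control array was 0.34 and the highest 0.43. Over all 4838 genes, however, control B correlated more closely with isometric A (r 0.971) than with control A (0.966). The 2 isometric arrays correlated at 0.965, so correlation did not separate these 2 pools. Both control arrays carry the same pooled RNA, so a deviation of that pool may still raise both differences together. An effect common to both kinds of contraction also stays open, as a hypothesis.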
